A study of Mus musculus with 6 samples.

How the data were processed

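Lens RNA of Tdrd7 null and Tdrd7 heterozygous mice at postnatal day 4 was labelled as biotinylated cRNA with the Illumina TotalPrep kit, per the labels' protocols, and measured on 6 bead arrays. The deposited raw table holds 1 intensity per probe and array on a linear scale, not normalised between arrays, per the file headers and from the values. It also holds a detection p-value for each intensity, per the file headers. The scanner software and its background step are not given in the sources used here. The authors also deposited a table of normalised intensity values by a method not given in the sources used here. From the values it is on a linear scale, not centred, and each of its columns is a straight line of 1 raw column, with a residual of at most 0.0097, a slope of 0.849 to 1.08 and a rank correlation of 1 against at most 0.827 with any other raw column. Its medians were 72.5, 72.76 and 72.65 for heterozygous replicates 1, 2 and 3 and 72.6, 74.15 and 72.98 for null replicates 1, 2 and 3.

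The raw columns name the genotype and no replicate number, so arrays are called a, b and c within a group in the order of the table, and these letters pair nothing. Each raw column matched a deposited column of the same genotype. The columns of the authors' table carry replicate numbers, and a fit with these numbers could be made on that table alone. Raw medians per array were 69 to 76.64 and 30.7% to 34.8% of probes were detected.

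Probes were named from the platform annotation. Of 45281 probes 34885 had 1 gene symbol, 18 had several and 10378 had none; those with several or none were tested but not named. The gene table of assembly GRCm38.p6 matched 34807 of them and changed 0 symbols. It served for names, neighbours and gene spans only.

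Intensity values were normalised with neqc in limma 3.58.1 (R 4.3.3): normexp with negative controls inferred from the detection p-values, whose steps imply 936 controls, an offset of 16, quantile normalisation and log2. Probes with a detection p under 0.05 on at least 3 of 6 arrays were kept. Null minus heterozygous was fitted with lmFit and eBayes without covariates, two-sided, with Benjamini-Hochberg adjustment over the 14636 probes and a threshold of 0.05. A gene is represented by its probe with the highest mean log2 signal, and probes that disagree in sign are given. Where a probe was detected on no array of one group, the fold is a lower bound: the mean of the brighter group against the dimmer group's mean of, per array, the higher of its own signal and the lowest signal of a detected probe. Gene lists with at least 4 measured members were tested with camera at a preset correlation of 0.01 and with an estimated correlation. The camera p-values were adjusted over 24 lists, while those of fry, run beside it, were left unadjusted. Beside camera, fry gave an unadjusted p of 0.0438 for heat shock proteins and chaperones and 0.0172 for glycolysis and hypoxia, in one direction. For oxidative stress genes, which camera did not call, fry gave an unadjusted p of 0.0493, also in one direction.

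Before the data were examined, 31 lists, the tests, most alternatives and the rule for named genes were fixed. The rule took Tdrd7, the 10 largest rises and 10 largest falls among passing genes with groups that do not overlap, filled up to 10 with the genes of smallest p among the rest with such groups, up to 4 members of each list and all 4 genes tied to Tdrd7 in earlier lens work. Frmpd1, Xpa and the snoRNA host genes other than Snhg12 and Snhg10 were named after their values were seen.

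Too few members were measured in 7 lists. Of the interferon response Irf9 differed by -0.38 and Ifitm3 by 0.29, of retina Rbp3 by -0.23, while Crx, detected on no heterozygous array, was at least 1.05-fold higher (adjusted p = 0.964), and of pigmented epithelium Oca2 by -0.10. Of macrophages Csf1r differed by 0.03, Aif1 by 0.07 and Lyz1 by -0.15, of cornea Upk1b by 0.53, Tkt by -0.33 and Ecm1 by 0.41, and of ciliary body and muscle Myl9 by 0.24, Zic1 by -0.04 and Col9a1 by 0.03. Of the sex-linked genes Xist differed by -1.32 and Eif2s3y by 1.30. None of these passed.

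The steps were tested on simulated data for the comparison of null with heterozygous lens. The 14636 probes were drawn at their measured means and with the variances as moderated by eBayes. These vary less between probes than the measured variances, so the rates need not hold for the most variable probes. Of 200 changed probes 13.4% were called at a fold of 1.5, 80.6% at a fold of 2 and 100% at a fold of 4, and 8 of 137 calls were false. In 20 draws with no change, 4 had any called probe and 1 any called list, over 8626 genes. A list shifted by a fold of 1.5 was called in 20 of 20 draws. The draws were independent between genes and held no array that stands apart. In the real lists the estimated correlation reached 0.657, so the rates for lists need not hold there. Alternatives covered the background step, normalisation, filter, variance model, array weights, probe choice, list correlation, window, threshold and each array left out. The chip was not analysed here as a block.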

Results

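Total RNA from the lens of mice at postnatal day 4 was measured on 6 Illumina bead arrays, 3 from Tdrd7 null and 3 from Tdrd7 heterozygous mice of a mixed strain background that includes C57BL/6J. Tdrd7 encodes a Tudor domain protein of cytoplasmic RNA granules, and its loss is known to cause cataract. Between 13901 and 15765 of the 45281 probes were detected per array, and 14636 probes naming 8626 genes were tested. The arrays of a group are named a, b and c here. The labels do not say whether the arrays of a group came from separate mice, so the p-values measure the spread between these arrays, and their number limits the precision.

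The first comparison asked whether the targeted transcript differed as the genotype labels say. Tdrd7 fell by 3.48 on the log2 scale (SE 0.153, adjusted p = 1.47e-05), an 11.17-fold lower signal in null lens. Its raw signal was 12861 ± 336 (SD, n = 3) in heterozygous lens and 1191 ± 82 (SD, n = 3) in null lens. The signal of Tdrd7 was lower on each of the 3 null arrays than on every heterozygous array, and it was still detected on all 3 null arrays. Whether the probe (ILMN_2818678) lies inside the mutated part of the gene was not analysed here.

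The second comparison asked which other genes differ between null and heterozygous lens. Snhg12, a noncoding host gene of small nucleolar RNAs, was the other transcript that changed. Snhg12 fell by 1.72 on the log2 scale (SE 0.168, adjusted p = 0.0118), and its raw signal was 4107 ± 201 (SD, n = 3) in heterozygous and 1296 ± 147 (SD, n = 3) in null lens. With limma, 2 probes passed, 0 of them higher and 2 lower in null lens, and the next smallest adjusted p was 0.296. At an unadjusted p under 0.05 there were 602 probes, 318 higher and 284 lower. This is 4.11% of those tested, below the share of 0.05 that chance gives. The values of the groups did not overlap for 10.9% of the probes, where chance gives 10%. The Snhg12 call was lost without heterozygous array a (adjusted p = 0.204), b (0.108) or c (0.169) and without the filter on dim probes (0.0842), and over all alternatives its adjusted p ran from 0.000776 to 0.204. The number of called probes became 1 without any of these heterozygous arrays, 4 without null array b and 13 with array weights. Those weights were 3.44, 0.208 and 0.79 for null arrays a, b and c, and 0.895 to 1.55 for the heterozygous arrays. The null group thus rested mainly on null array a in that fit. With these weights 1582 probes had an unadjusted limma p under 0.05, against 602 without them.

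**Figure D1:**
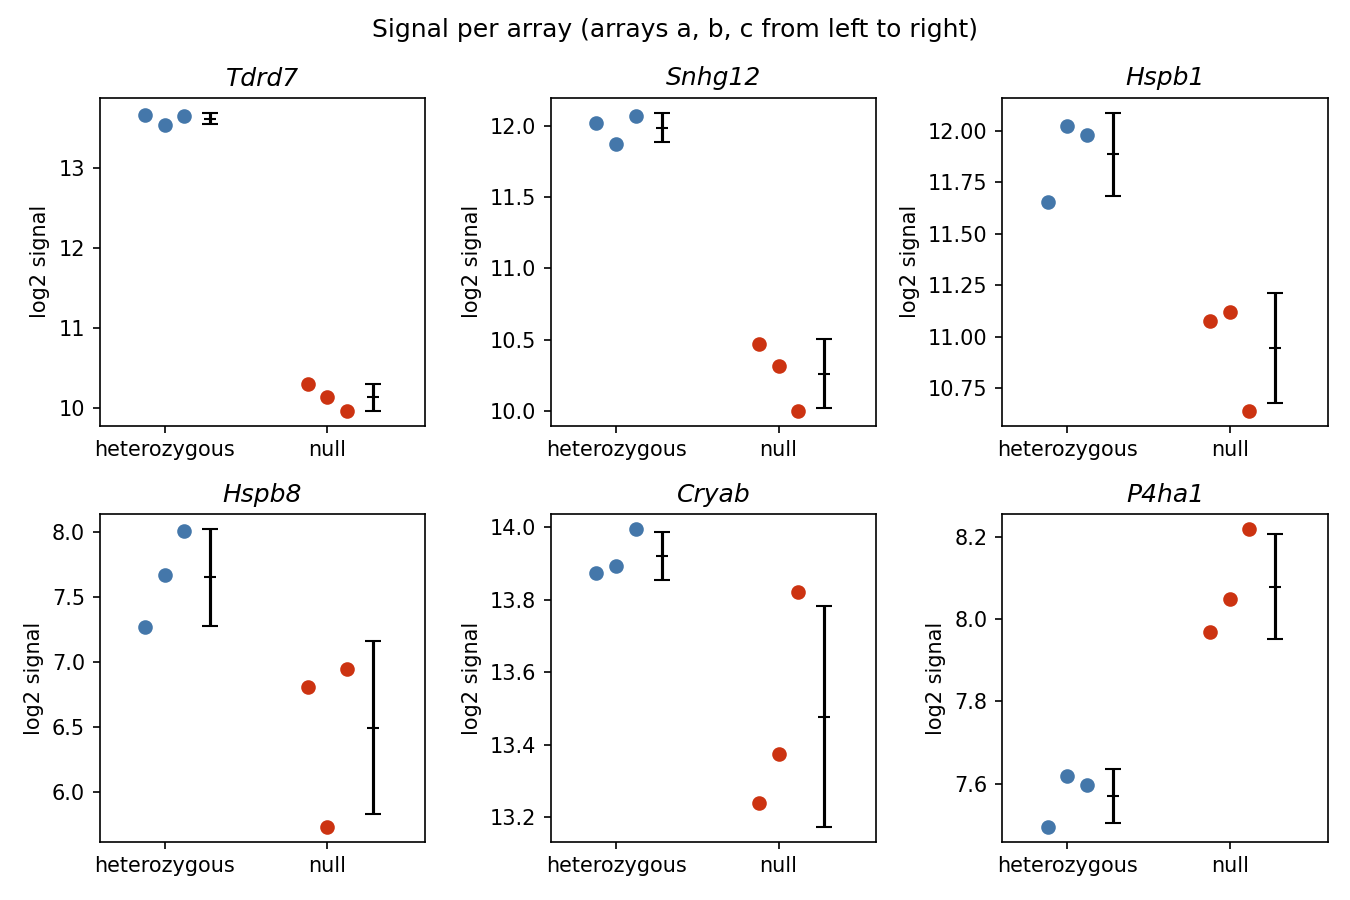
Normalised log2 signal (vertical axes, each panel with its own range) of 6 genes on each array, by genotype; points are arrays a, b and c from left to right, and the bar beside them is the mean with its SD. Tdrd7 and Snhg12 changed (log2 differences of -3.48 and -1.72), while Hspb1, Hspb8, Cryab and P4ha1 did not pass over all tested probes although their groups do not overlap.

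Among genes that did not pass but whose null arrays all lay below the heterozygous arrays, the smallest p-values belonged to 5430416N02Rik (log2 difference -0.97, SE 0.147), 2410006H16Rik (-1.19, SE 0.183) and Ppm1e, a protein phosphatase (-0.88, SE 0.14), each with an adjusted p of 0.296. AA467197 differed by -1.02, Hspb1 by -0.94, the snoRNA host gene Snhg10 by -0.85 and H2-Eb1, an antigen-presenting class II molecule, by -1.04. Fam171a1 differed by -0.64 and Fbxo10, an F-box protein gene, by -0.83. A second probe of Ppm1e gave -0.34 and one of Fam171a1 gave -0.32. With array weights the gene 2410006H16Rik (adjusted p = 0.00405), the gene 5430416N02Rik (0.0103), the gene Ppm1e (0.0103) and the gene AA467197 (0.0363) passed, and 2410006H16Rik also passed without null array b (0.0493). Over all alternatives the adjusted p of each of these 4 genes reached 1.

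In the other direction, Rgs5, a marker of pericytes, had the smallest p, with a log2 difference of 1.08 (SE 0.179, adjusted p = 0.363), and it was detected on 1 of 3 heterozygous and 3 of 3 null arrays. Wrn, a RecQ helicase, differed by 0.67, Kctd12 by 0.75, Gcg by 0.69, the splicing helicase gene Dhx8 by 0.69, Lipo3 by 0.57 and Retreg3 by 0.64. Slc22a2 (0.82) and the potassium channel gene Kcnma1 (0.76) were detected on 2 of 3 heterozygous arrays. A second probe of Kcnma1 gave -0.06 and one of Kctd12 gave 0.37. Man2a1, a Golgi mannosidase, was detected on no heterozygous array and was at least 1.37-fold higher in null lens (adjusted p = 0.964). None of these genes passed, and with array weights the gene Kctd12 (adjusted p = 0.021) and the gene Wrn (0.0404) did, where other alternatives gave adjusted p up to 1.

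With the preset correlation, heat shock proteins and chaperones were called as lower as a group in null lens, though not on every null array. Of 13 measured members 9 were lower and 4 higher, with a median log2 difference of -0.17 (camera, adjusted p = 0.0172). The call was lost when the correlation between genes was estimated (adjusted p = 0.516 with an estimated correlation). That correlation was 0.0417, and the unadjusted camera p was 0.043 with it against 0.000716 with the preset. How far correlation between members accounts for the lost call was not tested. Hspb1, a small heat shock protein, differed by -0.94 (SE 0.185) and Hspb8, another, by -1.16 (SE 0.315). Cryab, the small heat shock protein that is also a crystallin, differed by -0.44 and the co-chaperone gene Bag3 by -0.32. The null arrays of all 4 genes lay below the heterozygous arrays, and without null array b Bag3 differed by -0.20. Over all tested probes 0 members passed, and 2 passed adjusted over the list alone, Hspb1 (0.00676) and Hspb8 (0.0293). Hspb1 is also one of the genes tied to Tdrd7 in earlier lens work, so its fall is not independent evidence. A second Hspb8 probe gave -0.51. The list heat shock proteins and chaperones was not called without heterozygous array c (adjusted p = 0.107) or null array a (0.103), and its adjusted p ran from 0.00174 to 0.516 over the alternatives on the raw signals and the authors' values. The median member deviated from the mean of the other arrays by -0.39 on null array b, which stood apart from the rest, by -0.11 on null array a and by 0.10 on null array c, where it was not lower. On the heterozygous arrays it deviated by 0.13 to 0.16.

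Genes of glycolysis and hypoxia were called as higher as a group with the preset correlation. Of 17 measured members 13 were higher and 4 lower, with a median log2 difference of 0.20 (camera, adjusted p = 0.0199). With an estimated correlation the adjusted p was 0.516. That correlation was -0.0158, below the preset 0.01, so correlation between members does not account for the lost call. P4ha1, a collagen prolyl hydroxylase induced by low oxygen, differed by 0.51 (SE 0.147), Pgk1 by 0.37 and Ldha by 0.35, the last 2 being glycolytic enzymes. Without heterozygous array c Ldha differed by 0.15. Eno2, the neuronal enolase, differed the other way, by -0.62 (SE 0.186). Over all tested probes 0 members passed, and 0 passed adjusted over the list alone. A second probe of P4ha1 gave 0.19. The list glycolysis and hypoxia was not called without heterozygous array b (adjusted p = 0.0516), heterozygous array c (0.171) or null array a (0.103), without the filter (0.0992) or with the mean of a gene's probes (0.0943), and its adjusted p ran from 0.0037 to 0.516 over the alternatives. The median member deviated from the mean of the other arrays by 0.11, 0.22 and 0.10 on null arrays a, b and c and by -0.03, -0.21 and -0.13 on heterozygous arrays a, b and c.

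**Figure D2:**
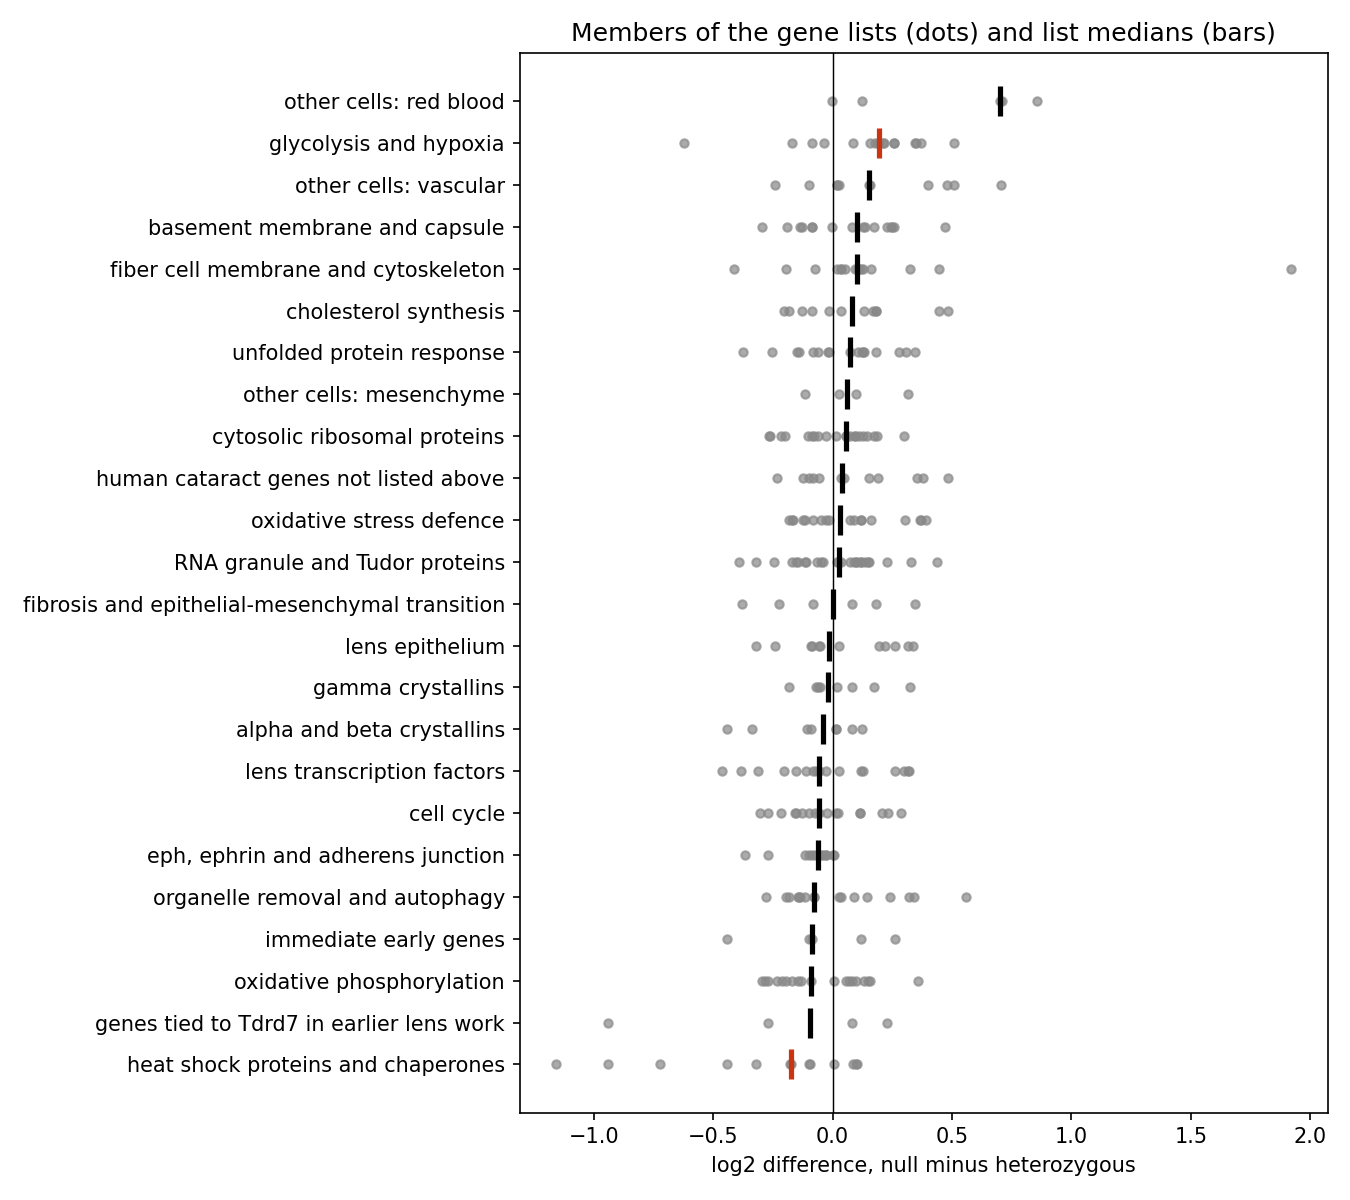
Log2 difference between null and heterozygous lens (horizontal axis) of each measured member (grey dots) of the 24 tested gene lists (vertical axis), with the list median as a bar, red where camera with its preset correlation gave an adjusted p under 0.05. The medians run from -0.17 for heat shock proteins and chaperones to 0.70 for red blood cell genes, and 2 lists have red bars.

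The other 22 lists were not called, and in all 24 lists 0 members passed over all tested probes. Adjusted over the list alone 2 genes passed, Hspb1 in 2 lists and Hspb8 in 1. Counted per list these are 3 members, against 6 without null array b and 8 without null array c. Neither class of crystallins, the main proteins of lens fibers, was called. Of the 8 alpha and beta crystallins 4 were higher and 4 lower (adjusted p = 0.606), with Cryab at -0.44, Cryaa at -0.34, Cryba2 at 0.12 and Crybb1 at -0.11. Of the 8 gamma crystallins 4 were higher and 4 lower (adjusted p = 0.871), with Crygf at 0.32, Crygd at -0.18, Crygs at 0.08 and Cryge at 0.18. Without null array b Cryaa differed by -0.07. Without null array c Crygf differed by 0.125 and Cryge by -0.199. In the authors' values Cryba2 (-0.04) and Crygs (-0.03) had the other sign, and a second Crygd probe gave 0.10. Of the 16 crystallin probes 13 had a mean raw signal above 20000, up to 50120, where the highest signal of an array was 49500 to 52870. A difference between such bright probes can be compressed. Quantile normalisation also gives the brightest probes of every array the same set of values, so a shift shared by these probes would be removed. The even splits are therefore no evidence that the crystallins were unchanged. Neither crystallin list was called with median scaling or with the authors' values, which use no quantile step. A change of the crystallins is not excluded.

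Fiber cell membrane and cytoskeleton genes included 13 higher and 3 lower members (adjusted p = 0.421). Among them Tmod1, an actin-capping tropomodulin whose gene lies 0.07 Mb from Tdrd7, differed by -0.41. Lctl differed by 0.32 and Sptbn1 by 0.44, with another Sptbn1 probe at -0.09. Lgsn, a lens glutamine synthetase-like gene, differed by 1.92 with an SE of 0.909 and overlapping groups, and the gene Lgsn differed by 0.58 without heterozygous array c, where it was not detected. Lens epithelium genes were 6 higher and 6 lower (adjusted p = 0.702), with Foxe3 at 0.32, Sfrp1 at 0.26, Fgfr2 at -0.32 and Dkk3 at -0.24. Other Fgfr2 probes gave 0.36 and 0.11, and other Dkk3 probes gave -0.11 and 0.03. Of the lens transcription factors 7 were higher and 10 lower (adjusted p = 0.906), with Mafg at -0.46, Tfap2a at 0.30 and Meis2 at -0.31, and a second Mafg probe at 0.02. Of the basement membrane and capsule genes 9 were higher and 7 lower (adjusted p = 0.421), with the collagen IV genes Col4a1 at 0.47, Col4a2 at 0.25 and Col4a3 at 0.25 and the proteoglycan gene Agrn at -0.295, and this list was called without heterozygous array a (adjusted p = 0.0188). Eph, ephrin and adherens junction genes were 2 higher and 10 lower (adjusted p = 0.49), with Efnb2 at -0.37, Epha5 at -0.12 and Efna5 at -0.10. Of the further human cataract genes, of which Lss and Cyp51 are also cholesterol synthesis genes, 7 were higher and 5 lower (adjusted p = 0.58), with Wfs1 at 0.35, Lss at 0.48, Chmp4b at 0.38 and Pxdn at 0.15. Of the genes in these lists, several differences rested on null array b: without it Meis2 differed by -0.02, Fgfr2 by -0.07, Dkk3 by -0.07, Efnb2 by -0.08, Agrn by -0.10, Sptbn1 by 0.16, Lss by 0.17 and Chmp4b by -0.07. Lens epithelium and mesenchyme markers were low on null array b (deviations of -0.41 and -0.48) and on heterozygous array c (-0.53 and -0.62).

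RNA granule and Tudor protein genes, the class of Tdrd7 itself, were 15 higher and 11 lower (adjusted p = 0.702). Fxr1, an RNA-binding protein of granules, differed by 0.44, Tia1 by -0.32, Tdrd3 by 0.23 and Stau1 by 0.33. The other 2 Tdrd3 probes gave 0.60 and 0.39, and without null array b Stau1 differed by 0.12. Of the genes tied to Tdrd7 in earlier lens work 2 were higher and 2 lower (adjusted p = 0.421): Hspb1 at -0.94, Epha2 at -0.27, Sparc at 0.23 and Crybb3 at 0.08. Of these 4 genes 1, Hspb1, passed adjusted over the list alone (0.00208). The list was called without null array b (adjusted p = 0.0467). That list was recalled from the study of this mouse and is not independent evidence of a direction. A second Crybb3 probe gave -0.24, the authors' values gave -0.07 for the gene Crybb3, and other Sparc probes gave -0.31 and 0.08. Without null array b Sparc differed by -0.01.

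Other groups of stress and metabolism were not called. Unfolded protein response genes were 9 higher and 8 lower (adjusted p = 0.702), with the chaperone genes Hsp90b1 at 0.34 and Sdf2l1 at 0.31, Chac1 at -0.38 and Asns at -0.25. Oxidative stress genes were 9 higher and 9 lower (adjusted p = 0.58), with the metallothionein Mt1 at 0.39, Gclc at 0.37, Srxn1 at 0.30 and Gsta4 at 0.37. Immediate early genes were 2 higher and 3 lower (adjusted p = 0.871), with Dusp1 at -0.44, Zfp36 at 0.26, Junb at 0.12 and Jun at -0.10. Organelle removal and autophagy genes were 8 higher and 9 lower (adjusted p = 0.865), with Bnip3l at 0.32, Wipi1 at 0.24, Becn1 at 0.56 and Gabarapl1 at 0.34. Without null array b Becn1 differed by 0.07 and Gabarapl1 by 0.05. Cholesterol synthesis genes were 7 higher and 5 lower (adjusted p = 0.554), among them Mvd at 0.44, Nsdhl at 0.17 and Fdps at 0.18. Oxidative phosphorylation genes were 9 higher and 10 lower (adjusted p = 0.702), with Sdhb at 0.36, Ndufb8 at -0.24, Ndufa4 at -0.29 and Cox4i1 at -0.21. Cytosolic ribosomal protein genes were 12 higher and 9 lower (adjusted p = 0.865), with Rps19 at 0.30, Rps14 at -0.26, Rpl27 at -0.27 and Rpl32 at -0.20. Cell cycle genes were 7 higher and 10 lower (adjusted p = 0.871), with Mcm2 at 0.29, Rrm2 at 0.23, Birc5 at -0.27 and Mcm4 at -0.30. A second Rrm2 probe gave -0.42. Fibrosis genes were 3 higher and 3 lower (adjusted p = 0.871), with Acta2 at 0.34, Tgfb2 at -0.38, Tnc at -0.22 and Tgfb1 at 0.18. Tgfb2 differed by -0.119 without heterozygous array a, Acta2 by 0.195 without heterozygous array c and Tnc by -0.106 without null array c. Without null array b Mvd differed by 0.16, Fdps by 0.04, Gsta4 by 0.14, Ndufa4 by -0.11, Cox4i1 by -0.10, Rpl27 by -0.11, Mcm4 by 0.02 and Tgfb1 by -0.05.

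Markers of other cells were not called with all arrays and the settings used here. Vascular genes were 9 higher and 2 lower (adjusted p = 0.0895), with the endothelial genes Cldn5 at 0.70, Flt1 at 0.51 and Esam at 0.40. Emcn, another endothelial gene, was detected on no heterozygous array and was at least 1.24-fold higher in null lens (adjusted p = 0.964). The vascular list was called as higher with array weights (adjusted p = 0.00976), without heterozygous array b (0.0376) and without null array c (0.0196). With all arrays and an estimated correlation, here 0.104, its adjusted p was 0.808. Red blood cell genes were 4 higher and 1 lower (adjusted p = 0.0943), with the globin genes Hba-a1 at 0.86, Hbb-bt at 0.71 and Hbb-bs at 0.70 and the band 3 gene Slc4a1 at 0.12. Without heterozygous array c the gene Hba-a1 differed by 0.41, the gene Hbb-bt by 0.25 and the gene Hbb-bs by 0.295. The median red blood cell gene deviated by -1.40 on heterozygous array c and by 0.88 and 0.69 on null arrays a and b. The red blood cell list was called as higher with the strict filter (adjusted p = 0.0448), without heterozygous array a (0.00717) and without null array c (0.0036). These calls used the preset correlation. With all arrays the estimated correlation was 0.618 and gave an adjusted p of 0.808. Mesenchyme genes were 3 higher and 1 lower (adjusted p = 0.702), with Mgp at 0.31, Fbln1 at -0.12, Igfbp5 at 0.10 and Col5a1 at 0.02. Other Fbln1 probes gave -0.05 and 0.01. The camera direction was upward where the median was below 0 for lens epithelium, organelle removal and gamma crystallin genes, and upward where the mean was below 0 for fibrosis genes.

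The third comparison asked whether differences gathered around the mutated locus, since the mice carry a mix of strains. Fbxo10 (-0.83), Frmpd1 (-0.62) and Xpa, a DNA repair gene (-0.58), were lower in null lens without passing the test over all probes. They lie within 20 Mb of Tdrd7 in the GRCm38.p6 gene table, with starts at -0.93, -0.78 and 0.21 Mb from its start. Tmod1, at 0.07 Mb, differed by -0.41 without passing, while other close neighbours were higher. As fewer than 20 genes passed, the 100 genes with the smallest p were counted. Of 121 genes near Tdrd7 4 were among them (3.31%), Tdrd7 included, against 96 of 8492 elsewhere (1.13%; two-sided Fisher's exact test, p = 0.0519). Within 10 Mb it was 4 of 78 (exact p = 0.0127) and within 40 Mb 4 of 164 (exact p = 0.123). Without Tdrd7 itself, a choice made after seeing the data, it was 3 of 77 within 10 Mb (exact p = 0.06), 3 of 120 within 20 Mb (exact p = 0.163) and 3 of 163 within 40 Mb (exact p = 0.44). The count of genes near Tdrd7 on its chromosome was 5 (exact p = 0.0131) without heterozygous array b or without null array a, and 2 (exact p = 0.653) without null array b. Over all alternatives the exact p ran from 0.0127 to 0.653.

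Arrays were then compared with each other. Null array b stood apart, with a mean Pearson correlation of 0.967 with the other arrays, where the others had 0.982 to 0.985. The first principal component held 50.6% of the variance and gave null array b a score of 45.8, against -14 to 0.3 for the rest. The SD of the log2 difference between null array b and the other null arrays was 0.477 and 0.526, against 0.283 between null arrays a and c and 0.272 to 0.322 among heterozygous arrays. Without null array b the differences of 49 of the 131 named genes shrank by over 1.5 times or turned, against 11 to 21 without any other array.

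**Figure D3:**
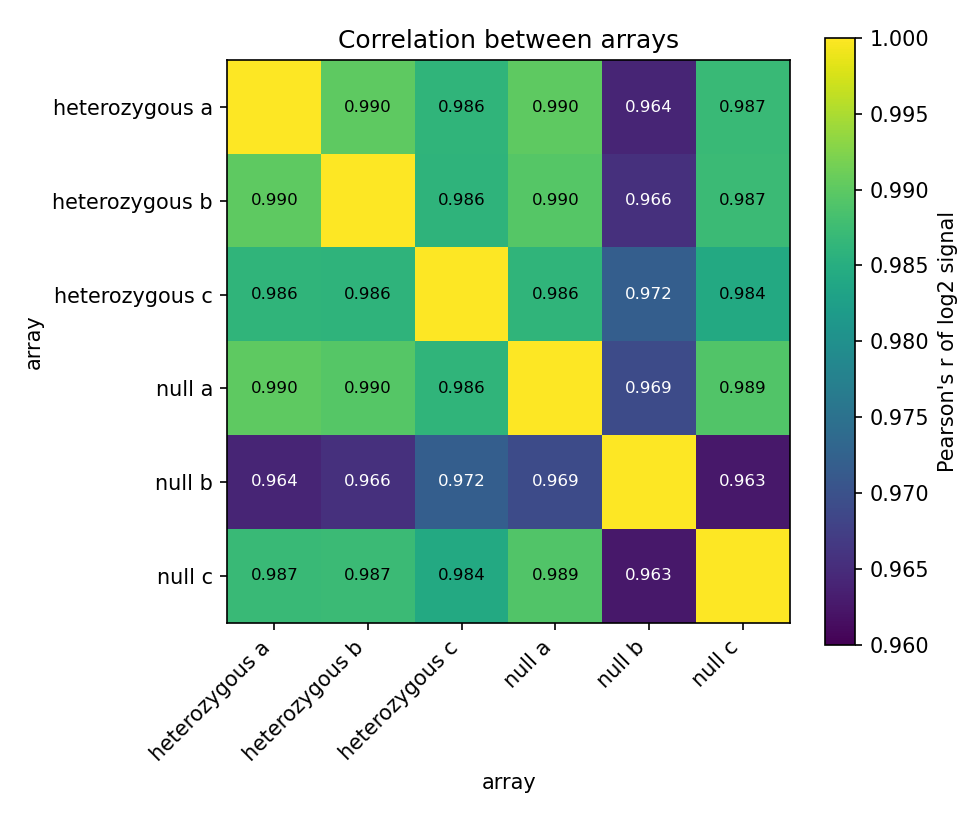
Pearson's r between the normalised log2 signals of each pair of arrays (both axes list the arrays; colour and printed number give r). Null array b has r of 0.963 to 0.972 with the others.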

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

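Tests on the replicate block and on Tdrd7 left out were chosen after the result was seen. Tdrd7 expression kept its direction and side of the threshold in all settings tried (log2 differences -3.56 to -3.37). Chip as a block was not run, since the columns name no chip. Signal over background limited the tests to probes detected on at least 3 arrays, and 30.7% to 34.8% of probes were detected per array. The called probes were 2 with the other background steps, median scaling, the authors' values, the strict filter, the trended variance and the fold of 1.5, and both were then shared with the 2 reported. They became 1 without the filter, which tests more probes, 13 with array weights (4 higher) and 96 at an unadjusted p and fold of 1.5 (50 higher); leaving out an array gave 1 to 4. Called lists became 3 with the strict filter (red blood added), 3 with array weights (vascular added), 1 without the filter, 1 with the mean of a gene's probes and 0 with an estimated correlation, and 0 to 4 with an array left out.

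The adjusted p of the list heat shock proteins and chaperones was 0.516 with an estimated correlation and 0.0036 to 0.107 with an array left out. For the list glycolysis and hypoxia it was 0.0992 without the filter, 0.0943 with the mean of a gene's probes, 0.516 with an estimated correlation and 0.0037 to 0.171 with an array left out. List members past the list alone numbered 5 without the filter, 10 with array weights and 2 to 8 with an array left out. The leading genes near Tdrd7 on its chromosome numbered 5 with normexp at an offset of 50 and with no background correction (exact p = 0.0131), 4 without the filter (0.0406), 4 with the strict filter (0.0414) and 4 within 10 Mb (0.0127), and 2 to 5 with an array left out. The mean correlation of null array b with the others was 0.973 with normexp at an offset of 50, 0.973 with no background correction, 0.974 for the authors' values, 0.979 without the filter and 0.960 with the strict filter, and 0.965 to 0.968 with another array left out. The cause was not tested for these, except where fewer or more probes or arrays entered.

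Replicate numbers did not pair the samples: same-numbered arrays of the authors' table had correlations of deviations of 0.16, -0.15 and -0.15, and not every array correlated best with its own number. With the replicate block on the authors' values, 1 probe, Tdrd7, and 5 lists were called. The lists were those for heat shock, glycolysis, red blood (adjusted p = 0.000208), vascular genes (0.0375) and alpha and beta crystallins (0.0198, lower). In that fit 8 members passed the list alone and 5 leading genes lay near Tdrd7. The mean correlation of the array that stood apart was 0.974. The gene Snhg12 kept its log2 difference of -1.73 with the block, but its call was lost (adjusted p = 0.163).

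Of 2066 comparisons of single named genes with an alternative, 2018 kept their direction and side of the threshold and 36 turned, none of the turned genes having passed. With the authors' values, with or without the replicate block, Cryba2 was -0.041, Crybb3 -0.065 and Crygs -0.025. With the mean of a gene's probes Crybb3 was -0.078, the gene Fgfr2 0.049, the gene Rrm2 -0.091 and the gene Tkt 0.043. With array weights Mcm4 was 0.051, Oca2 0.096, Slc4a1 -0.015 and Tgfb1 -0.117. With an array left out, the log2 differences ran from -0.011 to 0.121 for the gene Aif1, -0.067 to 0.667 for the gene Chmp4b, -0.081 to 0.203 for the gene Col5a1, -0.307 to 0.348 for the gene Col9a1, -0.199 to 0.519 for the gene Cryge, -0.041 to 0.104 for the gene Csf1r, -0.237 to 0.011 for the gene Epha5, -0.527 to 0.207 for the gene Fbln1, -0.322 to 0.481 for the gene Igfbp5, -0.555 to 0.022 for the gene Mcm4, -0.247 to 0.073 for the gene Oca2, -0.133 to 0.292 for the gene Slc4a1, -0.012 to 0.39 for the gene Sparc, -0.046 to 0.387 for the gene Tgfb1 and -0.207 to 0.169 for the gene Zic1.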

Other observations

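Among the tests below, those on probe noise, lens epithelium, the snoRNA host genes and the splits without Tdrd7 were chosen after the result was seen.

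Other snoRNA host genes lay beside Snhg12. Host genes were taken by symbol, Snhg or Gas5, after their values were seen. The array had 9 of them, and the 5 that were tested were all lower in null lens. A host gene under another symbol was not counted and could fall among the other noncoding genes below. Snhg5 differed by -0.59, Snhg18 by -0.275 and Snhg16 by -0.265, beside Snhg10 at -0.85 and Snhg12 at -1.72, and for 4 of the 5 every null array lay below every heterozygous array. Only Snhg12 passed over all probes. The median host gene was at -0.589, below the range of -0.301 to 0.159 that held the central 95% of medians of as many of the 78 other tested noncoding genes in 10000 draws. Snhg12 and Snhg10 had prompted this test, however, and the median of the remaining 3 host genes, -0.275, lay within the range of -0.351 to 0.248 for medians of 3 such genes. The other noncoding genes had a median of -0.06 (SD 0.303), and 44 of the 78 were lower. This argues against a general fall of noncoding transcripts as large as the median change of the host genes, and leaves it open for the 3 host genes that had not prompted the test. Of the host genes 0 lie within 40 Mb of Tdrd7, which argues only against a linked segment that ends within that distance. A longer segment linked to the locus was not tested and stays open, also for Snhg12. Strain variants elsewhere and an effect of the loss of Tdrd7 were not tested for these genes.

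Sex-linked genes differed between arrays of the same group. Eif2s3y, on the Y chromosome, had a log2 signal of 8.25 on heterozygous array b, 8.27 on null array a and 8.05 on null array b, and 4.26 to 4.62 on the other arrays. Xist, which silences an X chromosome in female cells, was 4.52 on null array b and 7.65 to 9.02 elsewhere. Heterozygous array b and null array a were thus high for both genes, as RNA of both sexes would give. Null array b alone was high for Eif2s3y only. Eif2s3y was detected on 1 of 3 heterozygous and 2 of 3 null arrays, so sex was not balanced between the groups. Sex was not a covariate, and its part in the differences and in null array b was not tested.

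Null array b may differ for technical reasons. Of 82 probes whose arrays fell into a high and a low set, apart by at least 1 log2 unit and by at least 3 times the range within either set, 75 had null array b alone on one side, among them Hdgf (2.00 above the mean of the other arrays) and Stub1 (1.80 above), with Tmx4 (-1.64) and Srsf3 (-1.60) below. Both probes of Hdgf (2.00 and 1.86) and of Tmx4 (-1.64 and -1.47) deviated alike. These probes are all among the 75 chosen for null array b standing alone, so their likeness is not evidence against noise. Independent noise of single probes adds no covariance between 2 probes of a gene, yet over 2884 genes that covariance was 0.0697 on null array b (95% bootstrap interval over genes 0.0582 to 0.0835) and at most 0.0229 on the others. This argues against such noise as the whole cause. Spearman's rho between the deviations of 2 probes was 0.298 on null array b, between the bounds set for it, and at most 0.31 on the others. A loss of long transcripts was tested by gene span, with a rho of -0.138 on null array b and at least -0.021 on the others across 8613 genes, which are not independent replicates; the value lay between the bounds set beforehand. Another share of lens epithelium was not excluded. That list deviated by -0.412 on null array b and by -0.527 on heterozygous array c, which did not stand apart although its deviation was as low. As the whole cause it would need the covariance of other arrays, scaled by the square of the ratio of their deviations, to reach that of null array b. Scaled from heterozygous array c the covariance was 0.0124, but with an upper bound of 0.163, and for 0 of the other arrays did the upper bound lie below the interval of null array b.

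Strain variants segregating between the mice could part the arrays by chance along the genotypes. Of the probes in a high and a low set, 2 parted 3 arrays from 3: 1 parted null from heterozygous arrays, Tdrd7 (Snhg12 missed the bound on the range within a set), and the highest number for any other split was 1, Eif2s3y, which parted heterozygous arrays a and c and null array c from the rest. These are too few to decide.

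The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. The genotypes gave 2 called probes and the highest other split 2, so 2 of the 10 splits had as many. That other split set heterozygous arrays a and c and null array c, the arrays with low Eif2s3y, against the rest. The genotypes gave 2 called lists and the highest other split 5, and 5 of the 10 splits had as many. They gave 4 leading genes near Tdrd7, the mutated gene itself among them, and the highest other split 3. Without Tdrd7 the genotypes gave 3 and the highest other split 3. At an unadjusted p under 0.05 in limma the genotypes gave 602 probes, and the other splits gave 261 to 1007.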
